A study of Homo sapiens with 15 samples.

How the data were processed

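RNA sequencing libraries of OVCAR5 cells and of subcutaneous OVCAR5 tumours from mice were compared. The values used were read counts per gene, deposited by the authors as 1 table for cells and 1 for tumours. Per the submitters' processing notes, cutadapt, Bowtie, STAR, HTSeq and DESeq2 were used with the builds hg19 and GRCh37. Their versions, roles and the strand setting of the counting are not given in the sources used here. Both tables hold whole numbers with HTSeq's summary lines for reads outside annotated exons, ambiguous reads and reads placed more than once, so the values were taken as raw counts without normalisation. Control columns are named GFP in the tables. The series' design text and the number of libraries per state differ, and the labels of the libraries themselves were followed.

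Each table lists 63677 Ensembl gene IDs. Names came from a table of gene names for 52181 IDs and from GENCODE 29 for 345, and 11151 IDs had no name, which held 1.11% of the counts in cells and 0.867% in tumours. All sample columns were used. The tables hold human gene IDs only, so reads from mouse cells that align to human genes cannot be recognised.

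Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, dispersions were estimated with the default settings of estimateDisp, and a quasi-likelihood fit with robust estimation took the 3 states as groups. The filter left 10704 genes in cells and 15107 in tumours, and the biological coefficient of variation was 0.147 and 0.0990. WT against control, DA against control and DA against WT were tested with two-sided quasi-likelihood F tests, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, as mean ± SD over libraries. No replicate block was used, because the labels do not say that a number marks a shared culture, mouse or day. In tumours, libraries of different states with the same number had residual correlations of -0.003 to 0.171. Those with different numbers had -0.174 to 0.073. Whether the numbers pair the tumours cannot be told from these values, and fits with a replicate block are given as an alternative. All 15 libraries were also fitted together over 14845 genes to test whether the effect of each construct differed between tumours and cells.

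Before the data were examined, 27 gene lists were fixed from textbook knowledge, 20 on pathways and 7 on other cell types, with the design of each test, most of the alternatives and the rule for named genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a contrast. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. With an estimated correlation 0 of the lists called were kept, and with fry 5 of 20 were. Lists with fewer than 2 tested genes were not tested.

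The rule names PTPRR, then the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups, passing over clone-based names and pseudogenes. Of each list it adds up to 4 called members with the smallest p, or up to 2 given as values where none was called. For the difference between tumours and cells it takes 4 genes per direction without the overlap condition. Of the genes that the rule names, 1 is not reported here.

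Shared calls of WT and DA were set against simulations in which no group differed, 10 for cells and 20 for tumours, analysed like the data with the same control libraries. For single values, exact two-sided permutation tests over libraries were used, whose smallest p is 0.333 for 2 against 2 libraries and 0.1 for 3 against 3.

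The pipeline was tested on simulated counts with the real means and library sizes. In cells 47.8% of 2-fold changes were recovered for WT and 44.8% for DA, and 100% and 93.9% of 4-fold changes. Of 1.5-fold changes 11.9% and 7.46% were recovered. In tumours 46.3% and 44.8% of 1.5-fold, 67.2% and 76.1% of 2-fold and 93.9% and 98.5% of 4-fold changes were recovered for WT and DA. False calls numbered 7 of 115 and 5 of 103 in cells, and 8 of 173 and 5 of 175 in tumours. A list shifted by 0.5 on the log2 scale was called in each, and of the unshifted lists 0 of 21 in cells and 0 of 23 in tumours. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called wrongly.

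Depth per library ran from 1393952 to 11931867 gene counts in cells and from 4734104 to 17258093 in tumours, where it goes with the group. The upper limit for a count of 0 is 3 counts of the library's total, which covers counting error only.

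The alternatives were RLE and upper-quartile scaling, no count filter, a filter at 1 CPM, no robust estimation, the replicate block, the compared groups alone, DESeq2 1.42.0, and leaving out each library in turn. Chosen after the data were seen were counts thinned binomially to the smallest library, offsets for GC content and transcript length (loess, span 0.5), protein-coding genes only, the share of reads outside annotated exons as a covariate, camera on the thinned, offset and covariate fits, fry in cells on genes called in tumours, and a replicate block on the 4 compared cell libraries as numbered and crossed. GC content and length were known for 10554 of 10704 genes in cells and 14741 of 15107 in tumours. The share of reads outside exons was higher in every WT tumour than in every control, control tumour 3 lay above the DA tumours, and the slope rests mainly on control tumour 3 against controls 1 and 2. An alternative that would separate mouse features was not run, since the tables hold none, and the offsets and the covariate were not run in the joint fit.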

Results

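The series measured RNA by sequencing in OVCAR5, a human ovarian cancer cell line, grown in culture or as tumours under the skin of mice. PTPRR encodes a receptor-type tyrosine phosphatase that can dephosphorylate MAP kinases. The labels name 3 states of the line: a control, PTPRR-WT and PTPRR-DA (written WT and DA here). What DA stands for is not given in the labels. Culture gave 2 libraries per state and tumours gave 3 per state, 15 libraries in all, whereas the series' design text gives 3 for cells and 2 for tumours. Tumours were collected about 20 days after injection. Total gene counts in cells were 1582790 and 1393952 in controls, 11931867 and 1571856 in WT, and 1843609 and 2085431 in DA. In tumours they were 5709340, 4810109 and 4734104 in controls, 9319177, 9694470 and 8678625 in WT, and 12530933, 16482442 and 17258093 in DA. A count of 0 allows up to 0.251 to 2.15 CPM (counts scaled to a common library size) in cells and 0.174 to 0.634 CPM in tumours, for counting error only. The p-values measure the spread between these samples, since nothing in the labels says whether the cell libraries came from separate cultures.

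PTPRR (ENSG00000153233) was higher in every WT and DA library than in every control library of the same setting. In cells it stood at 257 ± 62.7 CPM in controls (mean ± SD, n = 2), 3147 ± 158 CPM in WT (n = 2) and 2924 ± 123 CPM in DA (n = 2). In tumours it stood at 63.5 ± 1.99 CPM in controls, 2389 ± 73.3 CPM in WT and 2509 ± 90.9 CPM in DA (n = 3 each). The means differed 12.2-fold for WT and 11.4-fold for DA in cells, and 37.6-fold and 39.5-fold in tumours. WT and DA did not differ by the test in either setting, with a log2 fold change of -0.11 ± 0.19 in cells (± SE, adjusted p = 0.907, edgeR) and 0.07 ± 0.08 in tumours (adjusted p = 0.733, edgeR). The exact permutation test, two-sided, gave the smallest p that the design allows against the controls, 0.333 for n = 2 and 0.1 for n = 3. Reads of a construct and of the cell's own gene cannot be told apart in these counts.

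**Figure D1:**
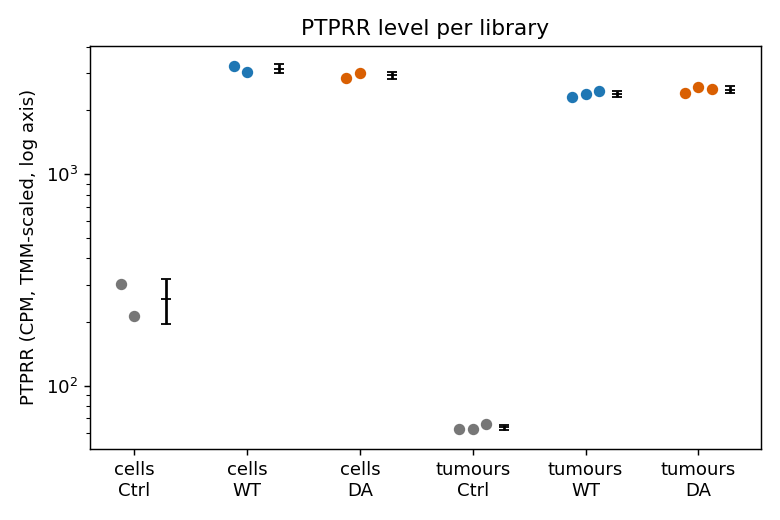
PTPRR in CPM after TMM scaling, on a log axis, 1 point per library, with the mean and SD of each group beside the points. Tumour controls average 63.5 CPM, and the WT and DA groups of both settings average between 2389 and 3147 CPM.

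The comparison of WT with control tumours asks which transcripts differ when cells carrying PTPRR-WT grow in a mouse. Glycolysis, hypoxia and p53 target genes fell as lists in WT tumours by camera at the preset correlation (n = 3 each). With an estimated correlation none of these list calls held (adjusted p = 0.383, 0.383 and 0.104), and with the share of reads outside exons in the model glycolysis and hypoxia were not called (adjusted p = 0.418 and 0.179). NDRG1, a stress gene induced by low oxygen, fell from 150 ± 20.9 to 81.1 ± 8.86 CPM, a log2 fold change of -0.88 ± 0.10 (adjusted p = 5.94e-05). Ribosomal protein genes fell as a group, among them RPL28 at -0.75 ± 0.10 (adjusted p = 0.000315). The group was not called with an estimated correlation (adjusted p = 0.383), and with the share of reads outside exons in the model its median was 0.04 (adjusted p = 0.792). VIM, the intermediate filament vimentin, fell from 589 ± 51.6 to 418 ± 27.4 CPM (-0.50 ± 0.09, adjusted p = 0.00274). Of 122 small nucleolar RNA (snoRNA) genes 24 rose and 2 fell, and of 60 small nuclear RNA genes 5 rose and 1 fell. RNU4ATAC, a minor-spliceosome RNA, rose by 3.61 ± 0.34 (adjusted p = 0.00391, 236 ± 36.3 against 19.2 ± 3.997 CPM).

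Of 15107 genes tested in tumours, 678 were called for WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 267 higher and 411 lower. Of these, 118 differed more than 2-fold, 87 higher and 31 lower, and the median size was 0.55 on the log2 scale. Protein-coding genes made up 395 of the genes that fell and 139 of those that rose. WT and control libraries did not overlap in CPM for 22.4% of genes, where chance gives 10%. The count moved with single libraries: it was 189 without control 1, 198 without control 2, 1212 without control 3, 369 without WT 1 and 183 without WT 2. With the replicate block it was 1123. The share of reads outside annotated exons was 38.9 ± 0.963% in WT and 30.7 ± 5.19% in control tumours (n = 3), and with that share in the model 5 genes were called, PTPRR among them.

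All 17 tested glycolysis genes had a negative fold change in WT tumours (median -0.35, camera adjusted p = 1.36e-06, adjusted p = 0.383 with an estimated correlation), and 5 of them fell over all genes, 13 adjusted over the list alone. PGAM1, a phosphoglycerate mutase, changed by -0.48 ± 0.10 (adjusted p = 0.0132). ALDOA, an aldolase, changed by -0.46 ± 0.11 (adjusted p = 0.0251), and ENO2, an enolase, by -0.49 ± 0.12 (adjusted p = 0.0256). The hypoxia list fell as well (25 of 27 members negative, median -0.26, camera adjusted p = 7.29e-06, adjusted p = 0.383 with an estimated correlation), with 3 members called over all genes and 9 adjusted over the list alone. P4HA2, a collagen prolyl hydroxylase, changed by -0.61 ± 0.15 (adjusted p = 0.0206) and SLC2A1, the main glucose transporter, by -0.60 ± 0.15 (adjusted p = 0.0314). With the share of reads outside exons in the model the medians of the glycolysis and hypoxia lists were -0.09 and -0.10.

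Of 69 ribosomal protein genes, 25 fell in WT tumours over all genes, and 35 fell and 1 rose adjusted over the list alone (median -0.35, camera adjusted p = 2.78e-11, adjusted p = 0.383 with an estimated correlation). RPL23A changed by -0.66 ± 0.10 (adjusted p = 0.000514), RPL18 by -0.63 ± 0.10 (adjusted p = 0.00133) and RPL32 by -0.70 ± 0.11 (1255 ± 101 against 2044 ± 382 CPM, adjusted p = 0.0017). Control 3, at a mean log2 CPM of 8.63 over the 69 genes, lay close to WT 1 at 8.60. Reads of these genes may be shared with their many pseudogenes. RPL28 stood at -0.41 ± 0.14 (adjusted p = 0.400) with the share of reads outside exons in the model. The respiratory chain list was not called (adjusted p = 0.203), though without control 3 it was (adjusted p = 0.0224), and its members went both ways. UQCRB, a subunit of complex III, rose by 0.70 ± 0.10 (adjusted p = 0.000438, 450 against 277 CPM). NDUFB3 of complex I rose by 0.66 ± 0.18 (adjusted p = 0.0402). ATP5PO, a subunit of ATP synthase, changed by -0.57 ± 0.09 (adjusted p = 0.00133). COX4I1 of complex IV changed by -0.58 ± 0.11 (adjusted p = 0.00411), ATP5PF of ATP synthase by -0.43 ± 0.11 (adjusted p = 0.0358) and NDUFV1 of complex I by -0.42 ± 0.12 (adjusted p = 0.0436). NDUFB3 and NDUFV1 were named after their values were seen. MRPL14, a mitochondrial ribosomal protein, changed by -1.05 ± 0.12 (adjusted p = 4.85e-05).

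The p53 target list fell in WT tumours (23 of 26 negative, median -0.28, camera adjusted p = 3.44e-05, adjusted p = 0.104 with an estimated correlation). CCNG1, a cyclin induced by p53, was the 1 member called over all genes, at -0.45 ± 0.12 (adjusted p = 0.0397), and 12 were called adjusted over the list alone. CCNG1 stood at 0.00378 ± 0.15 (adjusted p = 0.998) with the share of reads outside exons in the model, so its call ended and its value lay near 0. The p53 list itself kept its call there, with fry, on thinned counts, with the offsets and whichever single library was left out. The unfolded protein and ATF4 list fell (median -0.13, camera adjusted p = 0.0166, adjusted p = 0.383 with an estimated correlation). Over all genes 3 of 34 members were called, and 7 adjusted over the list alone. The 3 were SHMT2 and PHGDH, enzymes of serine and glycine metabolism, at -0.56 ± 0.12 (adjusted p = 0.0115) and -0.58 ± 0.13 (adjusted p = 0.0164), and the stress factor ATF3 at -0.68 ± 0.17 (adjusted p = 0.0374). The list was not called without control 1 (adjusted p = 0.0552), with offsets for GC content and length (adjusted p = 0.0503) or with the share of reads outside exons in the model (adjusted p = 0.438). GADD45B, a stress-induced growth arrest gene, changed by -1.30 ± 0.21 (adjusted p = 0.00141, 7.08 against 17.5 CPM). The cholesterol synthesis list fell (median -0.16, camera adjusted p = 0.0214, adjusted p = 0.456 with an estimated correlation). Over all genes 1 of 23 members was called, and 2 adjusted over the list alone. It was not called without control 1 (adjusted p = 0.259) or WT 3 (adjusted p = 0.0945), or on counts thinned to the smallest library (adjusted p = 0.106), and with the share of reads outside exons in the model its median was 0.0623 (adjusted p = 0.883).

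The epithelial junction list fell in WT tumours (median -0.13, camera adjusted p = 0.0133, adjusted p = 0.383 with an estimated correlation). Over all genes 2 of 19 members were called, and 2 adjusted over the list alone. These were KRT8 and KRT18, paired epithelial keratins, which changed by -0.47 ± 0.10 (adjusted p = 0.00946) and -0.57 ± 0.13 (adjusted p = 0.0145). NECTIN4, a cell adhesion molecule outside the lists, changed by -1.11 ± 0.18 (adjusted p = 0.00133, 7.54 against 16.2 CPM). The TGF-beta response list fell (median -0.13, camera adjusted p = 0.0465, adjusted p = 0.383 with an estimated correlation). Over all genes 1 of 17 members was called, KLF10 at -0.38 ± 0.10 (adjusted p = 0.0397), and 4 adjusted over the list alone. It was not called without control 1 (adjusted p = 0.128), control 2 (adjusted p = 0.0739) or WT 2 (adjusted p = 0.103), on thinned counts (adjusted p = 0.0641), with the offsets (adjusted p = 0.0995) or with the share of reads outside exons (adjusted p = 0.560). The ERK output list was not called (adjusted p = 0.131) but was without WT 1 (adjusted p = 0.038), and 4 of its 27 members fell. MYC, a growth-promoting transcription factor, changed by -0.46 ± 0.11 (adjusted p = 0.0238, 65.5 against 90.5 CPM). The survival gene MCL1 changed by -0.34 ± 0.08 (adjusted p = 0.0242). DUSP5, an ERK phosphatase, changed by -1.04 ± 0.29 (adjusted p = 0.0413) and SPRY2, a feedback inhibitor of receptor signalling, by -0.59 ± 0.16 (adjusted p = 0.0415). WLS, which carries Wnt proteins to the cell surface, changed by -0.45 ± 0.10 (adjusted p = 0.0178). In the cell cycle lists, TYMS, thymidylate synthase, changed by -0.52 ± 0.09 (adjusted p = 0.00271, 226 against 323 CPM). BIRC5, survivin, changed by -0.44 ± 0.10 (adjusted p = 0.0173).

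The remaining lists were not called for WT in tumours. Camera's adjusted p was 0.375 for Wnt targets (1 of 29 called, MYC), 0.653 for Wnt components (1 of 35), and 0.203 for MAPK phosphatases (1 of 8). Mesenchymal genes gave 0.292 (1 of 18, VIM). The p was 0.157 for G1/S genes (1 of 32) and 0.406 for G2/M genes (1 of 33). It was 0.826 for interferon-stimulated genes (0 of 25), 0.36 for NF-kB genes (0 of 13), 0.269 for YAP targets (0 of 21) and 0.269 for antigen presentation (0 of 9). Values below the threshold included NFKBIA, the NF-kB inhibitor, at -0.48 ± 0.15 (adjusted p = 0.0736), the peptide transporter TAP1 at -0.79 ± 0.30 (adjusted p = 0.132) and the YAP target CCN1 at -0.48 ± 0.15 (adjusted p = 0.0756). Adjusted over the list alone, the counts differed for NF-kB genes, where 2 fell. The median and the test differed in sign for Wnt components and NF-kB genes. Among WT calls, PTPRR, RNU4ATAC, GADD45B, NECTIN4, MRPL14, VIM, TYMS, NDRG1, UQCRB, ATP5PO, COX4I1, RPL28, RPL23A, RPL18 and RPL32 kept their call whichever single library was left out. Each other called gene that the naming rule gave lost it in at least 1 of the 9 such fits. With the share of reads outside exons in the model PTPRR alone of the 43 called genes from that rule kept its call, and the standard error was larger for all 43. Of the 42 that lost it, 7 had a fold change as large or larger than before. These were RNU4ATAC at 4.09 ± 0.70 (adjusted p = 0.247), SNHG12 at 1.96 ± 0.47 (adjusted p = 0.363), COL5A1 at -1.57 ± 0.40 (adjusted p = 0.233), ATP5PO at -0.63 ± 0.14 (adjusted p = 0.193), RNU6ATAC at 2.03 ± 0.62, SNORA75 at 2.21 ± 0.78 and ENO2 at -0.64 ± 0.20. The other 35 had smaller values, among them NDRG1 at -0.59 ± 0.15 (adjusted p = 0.243), VIM at -0.32 ± 0.13 (adjusted p = 0.475) and UQCRB at 0.60 ± 0.16 (adjusted p = 0.247). Some lay near 0, such as ALDOA at -0.00961 ± 0.142, BIRC5 at -0.10 ± 0.14, PHGDH at -0.10 ± 0.16 and COX4I1 at -0.12 ± 0.13. CCNG1 at 0.00378 ± 0.15 lay near 0 too, with a changed sign.

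**Figure D2:**
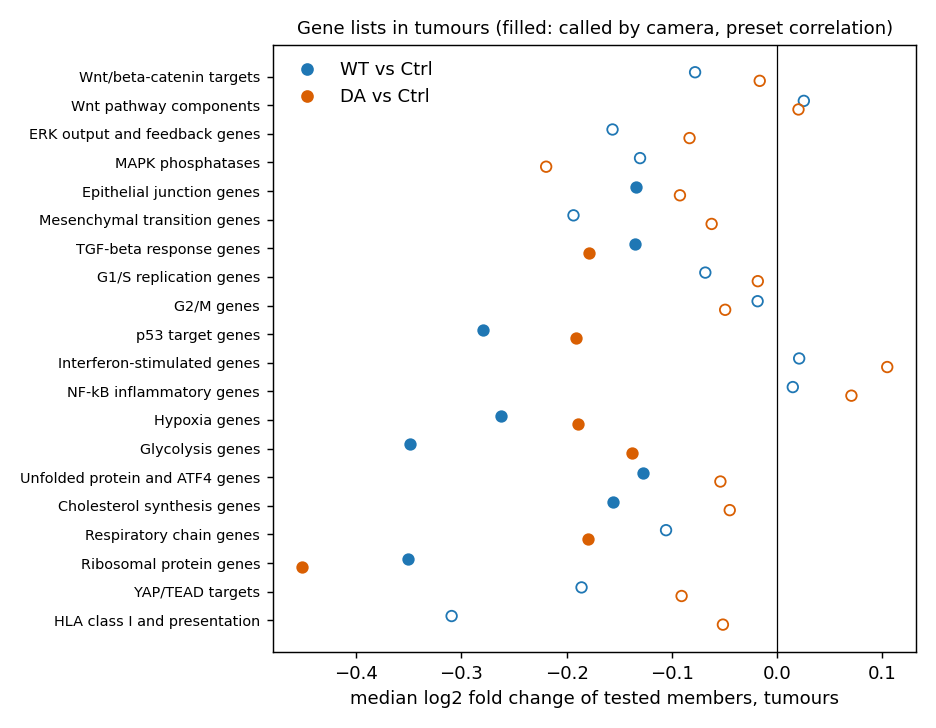
Median log2 fold change of the tested members of each gene list in WT and DA tumours against control tumours, with lists called by camera at the preset correlation filled. Ribosomal protein genes have medians of -0.35 in WT and -0.45 in DA.

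Small RNA genes stood out among the genes that rose in WT tumours. Of 267 genes that rose, 24 were snoRNA genes, 8.99% against 0.808% of all genes tested (122 of 15107, Fisher's exact test across genes, p = 1.11e-18), and 2 snoRNA genes were among those that fell. RNU6ATAC, another minor-spliceosome RNA, rose by 2.02 ± 0.31 (adjusted p = 0.0213, 203 against 49.9 CPM), SNORA66 by 2.65 ± 0.45 (adjusted p = 0.014), SNORA75 by 1.99 ± 0.38 (adjusted p = 0.0423) and SNHG12, a snoRNA host gene, by 1.83 ± 0.22 (adjusted p = 0.00526, 776 ± 174 against 218 ± 12.8 CPM). SNORA35B and SNORA19 changed by -1.51 ± 0.26 (adjusted p = 0.0275) and -1.06 ± 0.23 (adjusted p = 0.0164). KRTAP19-1, a hair keratin-associated protein gene, changed by -1.24 ± 0.26 (adjusted p = 0.0152). The mean log2 CPM of all snoRNA genes was 2.78, 2.97 and 2.82 in control tumours, 3.67, 3.58 and 3.51 in WT, and 3.73, 3.60 and 3.10 in DA. Most of these genes lie inside introns of other genes and the strand setting of the counting is not stated, so their reads cannot be told from unspliced host RNA, and SNHG12 is annotated antisense to another gene.

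The comparison of DA with control tumours asks the same of PTPRR-DA. Ribosomal protein genes fell as a list here too by camera at the preset correlation (n = 3 each), a call lost with an estimated correlation (adjusted p = 0.298). RPL23A went from 743 ± 100 to 380 ± 9.32 CPM (-0.97 ± 0.10, adjusted p = 1.1e-05) and RPS15A from 1031 to 521 CPM (-0.98 ± 0.13, adjusted p = 0.000721). NDRG1 fell to 90.3 ± 2.09 CPM (-0.73 ± 0.10, adjusted p = 0.000503), CCNG1 fell from 476 to 293 CPM (-0.70 ± 0.12, adjusted p = 0.00379) and TYMS changed by -0.56 ± 0.09 (adjusted p = 0.0017). RNU4ATAC rose by 3.75 ± 0.34 (260 ± 84.6 against 19.2 ± 3.997 CPM, adjusted p = 0.00396).

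For DA, 495 of 15107 genes were called by edgeR, 153 higher and 342 lower, 100 and 316 of them protein-coding. More than 2-fold differences numbered 74, 50 higher and 24 lower, and the median size was 0.53. Libraries did not overlap for 22.3% of genes (10% by chance). The count was 210 without control 1, 124 without control 2, 957 without control 3, 164 without DA 1, 273 without DA 2 and 276 without DA 3. With the replicate block it was 1072. The share of reads outside annotated exons was 35.0 ± 0.587% in DA tumours, and with it in the model 65 genes were called.

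Of the 69 ribosomal protein genes, 67 had a negative fold change in DA tumours (median -0.45, camera adjusted p = 6.07e-24, adjusted p = 0.298 with an estimated correlation). Of these, 32 fell over all genes and 53 adjusted over the list alone. RPS20 changed by -0.80 ± 0.10 (adjusted p = 8.12e-05, 233 against 406 CPM), RPL21 by -0.79 ± 0.10 (adjusted p = 0.000262) and RPS21 by -1.30 ± 0.20 (adjusted p = 0.0117, 357 ± 70.6 against 877 ± 228 CPM). The list kept its call with the share of reads outside exons in the model, where its mean difference was -0.27 ± 0.05, against -0.43 ± 0.10 without it. The respiratory chain list fell (median -0.18, camera adjusted p = 3.19e-05, adjusted p = 0.298 with an estimated correlation). Over all genes 6 of 43 members were called, and 15 adjusted over the list alone. ATP5PO changed by -0.56 ± 0.09 (adjusted p = 0.00154) and ATP5PF by -0.49 ± 0.11 (adjusted p = 0.0174). COX6A1 and COX7B, subunits of complex IV, changed by -0.46 ± 0.10 (adjusted p = 0.0116) and -0.42 ± 0.09 (adjusted p = 0.012). The hypoxia list fell (median -0.19, camera adjusted p = 6.24e-05, adjusted p = 0.518 with an estimated correlation; 1 of 27 called over all genes, 6 adjusted over the list alone). The glycolysis list fell (median -0.14, camera adjusted p = 0.00775, adjusted p = 0.698 with an estimated correlation). Over all genes 1 of 17 members was called, PGAM1 at -0.47 ± 0.10 (adjusted p = 0.0125) and 3 adjusted over the list alone. Glycolysis was not called without control 1 (adjusted p = 0.236) or DA 2 (adjusted p = 0.0683), nor with the share of reads outside exons in the model (adjusted p = 0.660).

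The p53 target list fell in DA tumours (median -0.19, camera adjusted p = 0.00291, adjusted p = 0.251 with an estimated correlation). CCNG1 was the 1 of 26 members called, both over all genes and adjusted over the list alone. The list lost its call only with the estimated correlation, not with fry, the other camera settings or any library left out. The TGF-beta response list fell (median -0.18, camera adjusted p = 0.0165, adjusted p = 0.251 with an estimated correlation). Over all genes 3 of 17 members were called, and 3 adjusted over the list alone. The 3 were ID2, an inhibitor of differentiation factors, at -0.70 ± 0.18 (adjusted p = 0.0373), SMAD7, an inhibitor of TGF-beta signalling, at -0.62 ± 0.16 (adjusted p = 0.0378) and KLF10 at -0.39 ± 0.10 (adjusted p = 0.037). It was not called without control 1 (adjusted p = 0.0886) or with the share of reads outside exons in the model (adjusted p = 0.194). VIM changed by -0.44 ± 0.09 (adjusted p = 0.00735) and BIRC5 by -0.53 ± 0.10 (adjusted p = 0.00521). SPRY2 changed by -0.59 ± 0.16 (adjusted p = 0.0395). The transcription factor SOX4 changed by -0.45 ± 0.10 (adjusted p = 0.0125), the Wnt corepressor TLE4 by -0.38 ± 0.08 (adjusted p = 0.0116) and WLS by -0.40 ± 0.10 (adjusted p = 0.0319). CCN1, a matricellular YAP target, changed by -0.76 ± 0.15 (adjusted p = 0.0062). SOD2, the mitochondrial superoxide dismutase, changed by -0.34 ± 0.08 (adjusted p = 0.03) and TM7SF2, a sterol reductase, by -1.10 ± 0.27 (adjusted p = 0.0289). OAS3, an antiviral synthetase, rose by 1.09 ± 0.27 (adjusted p = 0.0318, 6.83 against 3.25 CPM).

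Of the 153 genes that rose in DA tumours, 16 were snoRNA genes (10.5%, Fisher's exact test across genes, p = 9.08e-14), and 3 were among those that fell. SNORA66 rose by 2.69 ± 0.44 (adjusted p = 0.012), SNORA55 by 2.61 ± 0.39 (adjusted p = 0.0239, 129 against 21.1 CPM). RNU6ATAC rose by 2.33 ± 0.31 (adjusted p = 0.0136, 252 against 49.9 CPM) and a Y_RNA copy by 2.34 ± 0.49 (adjusted p = 0.0366). KRTAP19-1 changed by -1.56 ± 0.25 (adjusted p = 0.00396), RN7SKP255 by -1.43 ± 0.23 (adjusted p = 0.0116). RNVU1-34 changed by -1.38 ± 0.29 (adjusted p = 0.0473), SNORA35B by -1.35 ± 0.25 (adjusted p = 0.0392) and SNORA40B by -1.20 ± 0.24 (adjusted p = 0.0403). Copies of Y RNA and of small nuclear RNA are near-identical, so their counts are uncertain.

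The other lists were not called for DA in tumours. Camera's adjusted p was 0.949 for Wnt targets (1 of 29), 0.488 for Wnt components (2 of 35), 0.488 for ERK output (1 of 27), and 0.272 for MAPK phosphatases (0 of 8). Epithelial genes gave 0.492 (0 of 19). The p was 0.461 for mesenchymal genes (1 of 18), 0.678 for G1/S genes (1 of 32) and 0.0987 for G2/M genes (1 of 33). It was 0.585 for interferon-stimulated genes (1 of 25, OAS3) and 0.949 for NF-kB genes (1 of 13). Other values were 0.431 for unfolded protein genes (0 of 34), 0.272 for cholesterol synthesis (1 of 23), 0.74 for YAP targets (1 of 21) and 0.949 for antigen presentation (0 of 9). DUSP8 stood at -1.18 ± 0.36 (adjusted p = 0.0729) and DUSP5 at -0.88 ± 0.27 (adjusted p = 0.0729). Adjusted over the list alone, 3 Wnt components rose and 2 fell, 3 G1/S genes rose and 5 fell, and 3 ERK output, 2 MAPK phosphatase, 2 mesenchymal, 5 G2/M and 3 unfolded protein genes fell. The median, mean and test differed in sign for NF-kB and antigen presentation genes. PTPRR, RNU4ATAC, KRTAP19-1, VIM, TYMS, BIRC5, CCNG1, NDRG1, ATP5PO, RPL23A, RPS20, RPL21 and RPS15A kept their call whichever single library was left out, and each other named gene lost it in at least 1 of 9 such fits. In DESeq2 OAS3, KRTAP19-1, SNORA66, the Y_RNA copy, SMAD7, TM7SF2 and TTN were not called. Genes that DESeq2's own filter leaves without an adjusted p count as not called, so some of these may have been left out there. With the share of reads outside exons in the model PTPRR, NDRG1 (-0.57 ± 0.11, adjusted p = 0.0254), ATP5PO, RPL23A, RPS20, RPL21, RPS15A and SNORA40B kept theirs. Of the 30 named genes that lost it, 5 had a fold change as large or larger than before: RNU4ATAC at 4.01 ± 0.49 (adjusted p = 0.0600), RNU6ATAC at 2.34 ± 0.44 (adjusted p = 0.151), SMAD7 at -0.79 ± 0.19 (adjusted p = 0.0713), RNVU1-34 at -1.44 ± 0.40 and TTN at 0.92 ± 0.31. The other 25 had smaller values, among them SNORA55 at 2.56 ± 0.56 (adjusted p = 0.186), CCNG1 at -0.45 ± 0.11 (adjusted p = 0.0713) and VIM at -0.35 ± 0.09 (adjusted p = 0.116).

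**Figure D3:**
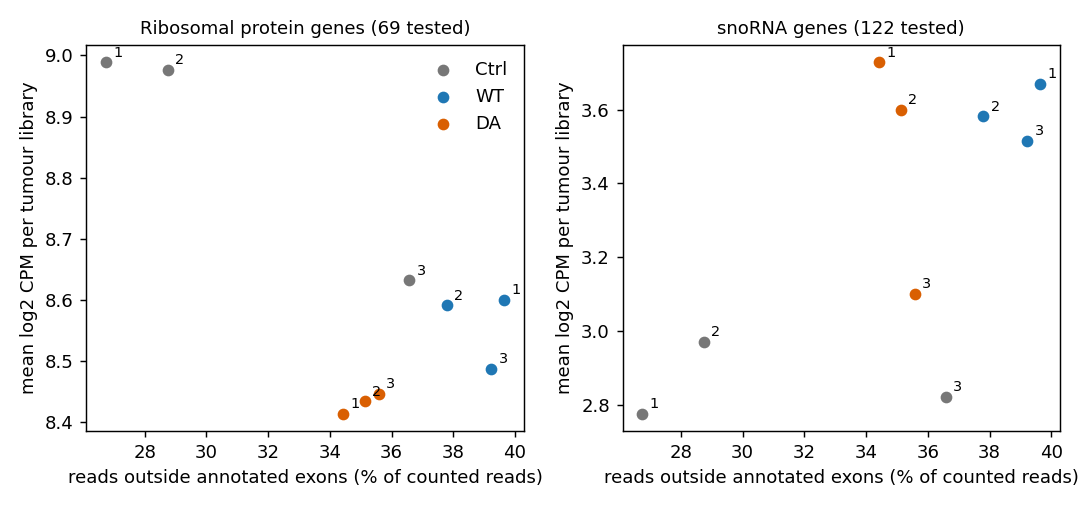
Mean log2 CPM of ribosomal protein genes (left) and snoRNA genes (right) in each tumour library, against the percent of all reads in the count table that lay outside annotated exons. Control 3, at 36.6%, has a mean of 8.63 for ribosomal protein genes and 2.82 for snoRNA genes.

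WT and DA tumours shared 225 calls against the common controls, 64 higher and 161 lower, and 0 genes were called in opposite directions. Among them were NDRG1, VIM, TYMS, CCNG1, BIRC5, KLF10, SPRY2, WLS, PGAM1, ATP5PO, RPL23A and RNU4ATAC. Independent calls would give 2.70 and 9.30 genes, and 20 simulations of unchanged groups against the same controls gave 0 shared calls. Unchanged groups give few calls by construction, so that 0 does not measure what the shared controls add. Across genes, which are not independent, the log2 fold changes had a Pearson correlation of 0.689, where the simulations gave 0.630, and the same sign for 73.6% of genes, where they gave 70.2%. Their covariance was 0.121, against 0.0435 ± 0.00169 (SD). The simulations drew each gene independently, so this SD leaves out variation that genes share within a library. In cells, where PTPRR was the 1 shared call, each measure lay below its simulated value. The correlation was 0.418 against 0.573, the same sign was found for 61.3% against 69.0% of genes, and the covariance was 0.0439 against 0.0618 ± 0.00115 (SD, 10 simulations). The simulations thus did not match the data in cells, and the excess in tumours does not measure sharing beyond the controls. The 3 tumour controls are too few to give each contrast its own, so part of the overlap may come from the shared control libraries.

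Setting DA against WT tumours asks whether the forms differ from each other. Respiratory chain genes were lower in DA than in WT as a list by camera at the preset correlation (n = 3 each), with 3 of 43 members called. The list was not called with an estimated correlation (adjusted p = 0.520) or with fry (adjusted p = 0.256). COA6, an assembly factor of complex IV, stood at -0.91 ± 0.17 (adjusted p = 0.0159), SDHD of complex II at -0.74 ± 0.15 (adjusted p = 0.0278, 16.0 against 26.6 CPM). COX7B stood at -0.51 ± 0.09 (adjusted p = 0.013) and UQCRB at -0.52 ± 0.10 (adjusted p = 0.0201). SNRPE, a core snRNP protein, was lower at -0.75 ± 0.13 (adjusted p = 0.0201, 115 against 194 CPM). TPM2, a tropomyosin, was higher at 0.64 ± 0.13 (adjusted p = 0.0355, 41.3 against 26.5 CPM). So was the transcriptional corepressor NACC2 at 0.60 ± 0.12 (adjusted p = 0.023). RRP12, a factor of ribosome assembly, stood at 0.56 ± 0.11 (adjusted p = 0.0201) and the centromere protein CENPB at 0.57 ± 0.13 (adjusted p = 0.0496). Higher too were GTF3C5, a subunit of a factor for RNA polymerase III, at 0.55 ± 0.13 (adjusted p = 0.0491) and LENG1 at 0.68 ± 0.15 (adjusted p = 0.0448). The small RNA genes SNORD15B, SNORD11 and SCARNA9 were lower, at -0.96 ± 0.17 (adjusted p = 0.035), -0.83 ± 0.14 (adjusted p = 0.0201) and -0.77 ± 0.12 (adjusted p = 0.0105), SCARNA9 being annotated antisense to another gene.

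Between the forms, 82 genes were called by edgeR, 21 higher and 61 lower in DA, 24 of them more than 2-fold. Libraries did not overlap for 21.7% of genes (10% by chance). Of the 61 lower genes, 14 were processed pseudogenes (Fisher's exact test across genes, p = 1.37e-08). The count was 51 without WT 1, 0 without WT 2, 386 without WT 3, 1 without DA 1, 48 without DA 2 and 19 without DA 3, and every gene named here lost its call without WT 2. DESeq2 called 206 genes on all 9 libraries, and 2172 genes had an unadjusted p under 0.05 in edgeR. The count was 403 with the replicate block, 381 with no count filter, 146 with the compared groups alone and 47 on thinned counts. It was 48 with the share of reads outside exons in the model, 20 of them among the 82. Of the 16 genes that the naming rule gave, COA6, COX7B, RPL23 and RPS27A kept their call there and 12 lost it, 4 of these with a fold change as large or larger. The 4 were SDHD at -0.77 ± 0.18 (adjusted p = 0.0691), SNRPE at -0.77 ± 0.18 (adjusted p = 0.123), SNORD15B at -1.08 ± 0.22 (adjusted p = 0.102) and SNORD11 at -0.84 ± 0.20 (adjusted p = 0.140). The other 8 had smaller values, among them UQCRB at -0.48 ± 0.11 (adjusted p = 0.0669) and TPM2 at 0.47 ± 0.15 (adjusted p = 0.174).

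By lists, DA tumours had higher glycolysis genes than WT tumours (median 0.15, camera adjusted p = 0.00512, adjusted p = 0.552 with an estimated correlation; 0 of 17 called over all genes, 3 adjusted over the list alone). They also had higher epithelial junction genes (median 0.13, camera adjusted p = 0.0264, adjusted p = 0.52 with an estimated correlation; 0 of 19 and 3). Respiratory chain genes were lower (median -0.06, camera adjusted p = 0.00512, adjusted p = 0.52 with an estimated correlation; 3 of 43 and 7), as were ribosomal protein genes (median -0.15, camera adjusted p = 0.000846, adjusted p = 0.552 with an estimated correlation; 2 of 69 and 8). RPL23 stood at -0.55 ± 0.10 (adjusted p = 0.0159) and RPS27A at -0.44 ± 0.09 (adjusted p = 0.0355). Glycolysis was not called without WT 2 (adjusted p = 0.0643) or DA 1 (adjusted p = 0.074), nor with the offsets (adjusted p = 0.06) or the share of reads outside exons in the model (adjusted p = 0.524). Epithelial genes were not called without WT 1 (adjusted p = 0.0933) or DA 3 (adjusted p = 0.0826), or on thinned counts (adjusted p = 0.063). Values short of the threshold included MYC at 0.37 ± 0.11 (adjusted p = 0.127), KRT8 at 0.36 ± 0.10 (adjusted p = 0.0825) and the glycolytic kinase PFKL at 0.47 ± 0.14 (adjusted p = 0.141). The remaining lists were not called, with camera's adjusted p at 0.317 for Wnt targets, 0.14 for Wnt components, 0.242 for ERK output and 0.972 for MAPK phosphatases. It was 0.825 for mesenchymal genes, 0.765 for TGF-beta response, 0.209 for G1/S, 0.254 for G2/M, 0.14 for p53 targets and 0.651 for interferon genes. The others were 0.22 for NF-kB, 0.36 for hypoxia, 0.0641 for unfolded protein, 0.209 for cholesterol, 0.276 for YAP and 0.14 for antigen presentation genes. Without WT 1 the p53 and antigen presentation lists (adjusted p = 0.0438 each) and the hypoxia list (adjusted p = 0.0389) were called, and the unfolded protein list was without WT 3 (adjusted p = 0.0371) or DA 2 (adjusted p = 0.0299). Adjusted over the list alone, 3 Wnt components were higher and 1 lower, and 2 unfolded protein and 2 cholesterol genes were higher. The median, mean and test differed in sign for MAPK phosphatases and TGF-beta response genes.

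Markers of other cells were sparse in the tumour libraries, which were counted on human gene IDs. Summed fibroblast markers stood at 122 ± 45.1 CPM in control, 125 ± 16.0 in WT and 145 ± 16.6 in DA tumours (n = 3 each), and muscle markers at 14.6 ± 5.93, 18.7 ± 2.23 and 23.9 ± 3.05 CPM. Endothelial markers summed to 2.86, 3.39 and 4.45 CPM, leukocyte markers to 3.67, 3.88 and 6.14, and blood markers to 0.0584, 0.142 and 0.595. In control, WT and DA cells in culture fibroblast markers summed to 46.5, 52.6 and 38.2 CPM and muscle markers to 5.04, 5.61 and 4.81. Leukocyte markers were also lower in cells (1.71, 1.67 and 3.27 CPM) than in tumours of each state, whereas keratinocyte markers were higher. The leukocyte sums in control and WT cells were near the limit for a count of 0, up to 2.15 CPM in cells. Endothelial markers summed to 4.76, 3.46 and 5.17 CPM in cells, with no clear difference for WT (3.46 ± 0.506 in cells and 3.39 ± 0.225 in tumours). Whether reads from the host add to the tumour sums was not tested. COL5A1, a fibrillar collagen, was lower in WT tumours (-1.11 ± 0.27, adjusted p = 0.0219), the only call among 9 tested fibroblast genes. TTN, the giant muscle protein titin, was higher in DA tumours (0.88 ± 0.24, adjusted p = 0.0455, 6.88 against 3.68 CPM), the only one among 3 muscle genes. TTN kept its call in 1 of 9 fits that left out a library. Camera's adjusted p for WT, DA and DA against WT was 0.826, 0.208 and 0.0984 for fibroblast, 0.36, 0.0737 and 0.209 for muscle, and 0.36, 0.366 and 0.0554 for adipocyte genes (2 tested). Without control 3 the fibroblast (adjusted p = 0.0201) and muscle (adjusted p = 0.0114) lists were called for DA, muscle also without DA 3 (adjusted p = 0.0428). Between the forms the fibroblast list was called without WT 3 (adjusted p = 0.0371) and the adipocyte list without control 1 (adjusted p = 0.0222). The fibroblast list, with the share of reads outside exons in the model, was called lower in WT than in control (adjusted p = 0.0178) and higher in DA than in WT (adjusted p = 0.000181), as were the muscle (adjusted p = 0.0138) and adipocyte (adjusted p = 0.037) lists. On thinned counts the muscle list was called for DA (adjusted p = 0.0409). With fry the adipocyte list was called higher in DA than in control (adjusted p = 0.040) and than in WT (adjusted p = 0.0109). Adjusted over the list alone, 1 muscle gene was higher in WT and 2 in DA, and 1 fibroblast and 1 adipocyte gene were higher in DA than in WT. Endothelium, leukocyte and keratinocyte lists had 1 tested gene each and 0 called over all genes. The leukocyte phosphatase PTPRC stood at 1.75 ± 0.55 in DA (adjusted p = 0.08). As the only tested gene of its list, it passed the threshold over the list alone without any adjustment. No blood gene passed the count filter.

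In cultured cells the comparison of WT with control asks what PTPRR-WT changes outside a host. PTPRR was the only gene called of 10704 (log2 fold change 3.61 ± 0.21, adjusted p = 1.09e-07, n = 2 each). Uncalled values included the keratins KRT18 at -0.65 ± 0.20 and KRT8 at -0.60 ± 0.22, and NDUFB8 of complex I at 0.96 ± 0.27 (adjusted p = 0.818 each, edgeR). Others were the ERK pathway inhibitor SPRED1 at 1.08 ± 0.37, the transcription factor FOS at -0.97 ± 0.41, the stress factor XBP1 at -0.64 ± 0.21 and HLA-C, an antigen-presenting protein, at -0.69 ± 0.26 (adjusted p = 0.818 each, edgeR). DESeq2 also called 1 gene, and 623 had an unadjusted p under 0.05 in edgeR. Without WT 2, 432 genes were called, 120 higher and 312 lower, the lone WT library being assumed to vary like the others. That library, WT 1, held 11931867 counts and lay at 32.1 on the first principal component (27.7% of the variance), the others between -15.6 and 6.34. On the second (26.4%) control 2 lay at 27.6 and the others between -15.2 and 10.3. WT and control libraries did not overlap for 30.4% of genes (33.3% by chance).

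PTPRR was likewise the only gene called for DA in cells by edgeR (3.50 ± 0.21, adjusted p = 1.62e-07, n = 2 each), with 208 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 30.5% of genes without overlap (33.3% by chance). EGR1, an immediate-early gene, stood at 1.05 ± 0.35 (26.0 against 12.3 CPM), CYCS, cytochrome c, at 0.48 ± 0.18 (283 against 203 CPM), ID3 at 1.33 ± 0.58 and HSD17B7, a sterol enzyme, at 1.37 ± 0.52 (adjusted p = 1 each). Respiratory chain genes rose as a list (34 of 42 positive, median 0.15, camera adjusted p = 0.025, adjusted p = 0.793 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. It was not called without control 1 (adjusted p = 0.781) or DA 2 (adjusted p = 0.1). With the share of reads outside exons in the model its adjusted p was 0.0876.

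Between DA and WT cells edgeR called 0 genes, with 848 at an unadjusted p under 0.05, DESeq2 called 0, and 38.9% of genes had no overlap (33.3% by chance). Without WT 2, 547 were called. Glycolysis genes were higher in DA as a list (15 of 17 positive, median 0.15, camera adjusted p = 0.00652, adjusted p = 0.899 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. It was not called without WT 2 (adjusted p = 0.3998) or DA 1 (adjusted p = 0.118). KRT18 stood at 0.92 ± 0.20 (adjusted p = 0.513), XBP1 at 0.74 ± 0.21 (adjusted p = 0.576), NDUFB8 at -0.93 ± 0.26 (adjusted p = 0.576), TGFB1 at 0.63 ± 0.20 and the death receptor TNFRSF10B at 0.56 ± 0.20 (adjusted p = 0.597 each). Adjusted over the list alone, KRT18 was higher in DA than in WT. KRT10, a skin keratin, was the only tested gene of its list, so nothing was adjusted there. It was lower in WT than in control and higher in DA than in WT by edgeR's unadjusted p alone, which was under 0.05 for 623 and 848 genes.

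The other lists in cells had no call. For WT, DA and DA against WT, camera's adjusted p was 0.983, 0.57 and 0.857 for Wnt targets, 0.983, 0.736 and 0.873 for Wnt components, and 0.983, 0.57 and 0.861 for ERK output. It was 0.983, 0.57 and 0.861 for MAPK phosphatases, 0.983, 0.598 and 0.861 for epithelial genes, 0.983, 0.765 and 0.873 for mesenchymal genes, and 0.867, 0.796 and 0.873 for TGF-beta response. Cell cycle lists gave 0.983, 0.992 and 0.948 for G1/S and 0.867, 0.57 and 0.948 for G2/M. The p was 0.867, 0.679 and 0.422 for p53 targets, 0.983, 0.764 and 0.873 for interferon, and 0.983, 0.57 and 0.861 for NF-kB genes. It was 0.353, 0.524 and 0.861 for hypoxia and 0.867, 0.765 and 0.861 for unfolded protein genes. It was 0.867, 0.239 and 0.861 for cholesterol, and 0.867, 0.57 and 0.257 for ribosomal protein genes. The last were 0.983, 0.634 and 0.861 for YAP, 0.263, 0.57 and 0.781 for antigen presentation and 0.983, 0.159 and 0.161 for fibroblast genes. Glycolysis gave 0.263 for WT and 0.349 for DA, and was called lower in WT without control 1 (adjusted p = 0.0299) and higher in DA without control 2 (adjusted p = 0.0215). Respiratory chain genes gave 0.983 for WT and 0.0537 for DA against WT, and were called without control 1 (adjusted p = 0.042) or control 2 (adjusted p = 0.0397), on thinned counts (adjusted p = 0.0442) or with the offsets (adjusted p = 0.0405). The median, mean and test differed in sign for Wnt targets, Wnt components, epithelial, G1/S, interferon, respiratory chain and YAP genes for WT, for TGF-beta response, G1/S and unfolded protein genes for DA, and for MAPK phosphatases, G1/S, G2/M and cholesterol genes between DA and WT. The adipocyte and keratinocyte lists had 1 tested gene each, and the endothelium, leukocyte, blood and muscle lists had 0.

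Testing the difference itself, in all 15 libraries and 14845 genes, the WT effect differed between tumours and cells for 14 genes, 11 with the higher value in tumours. PTPRR differed by 1.61 ± 0.20 (adjusted p = 0.00012). SNHG12 differed by 2.09 ± 0.29 (1.82 in tumours and -0.27 in cells, adjusted p = 0.00207), SNORA31B by 1.93 ± 0.30 (adjusted p = 0.00207), SNORD59A by 1.81 ± 0.32 (adjusted p = 0.0319) and GCSH, a protein of glycine cleavage, by 2.37 ± 0.45 (adjusted p = 0.0393). TCAF1, a regulator of an ion channel, differed by -1.75 ± 0.36 (adjusted p = 0.0485), BNIP1, a membrane fusion protein, by -1.70 ± 0.33 (adjusted p = 0.0319) and PABPN1, a nuclear poly(A)-binding protein, by -1.18 ± 0.23 (adjusted p = 0.0336). For DA, PTPRR was the only gene, at 1.80 ± 0.20 (adjusted p = 1.35e-05, 5.31 in tumours and 3.51 in cells). PTPRR stood at 257 CPM in cell controls and 63.5 CPM in tumour controls, scaled within each setting. In WT and DA it was 3147 and 2924 CPM in cells and 2389 and 2509 CPM in tumours. Its larger fold changes in tumours thus go with lower controls, not with higher levels in WT or DA. The WT count was 3 without cell control 1, 6 without cell control 2, 1 without cell WT 1, and 926 without cell WT 2. It was 6, 5 and 49 without tumour controls 1, 2 and 3, 5, 7 and 42 without tumour WT 1, 2 and 3, and 8 without tumour DA 2. The DA count was 2 without cell WT 1 or cell WT 2, 19 without tumour control 3, 3 without tumour WT 1, 2 without tumour DA 1 and 3 without tumour DA 3. Only PTPRR was called in both settings for the same contrast. Of the other genes, those called in WT tumours had the same sign in cells for 59 of 178 that rose (33.1%) and 226 of 393 that fell (57.5%), in DA for 58 of 118 (49.2%) and 144 of 323 (44.6%). Over all genes tested in cells 50.5% had a positive and 49.5% a negative fold change, for WT and for DA alike.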

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

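Of the tests here, those of the other splits of the libraries were planned, and those of depth, of GC content and length and of reads outside exons were chosen after the results were seen.

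Ribosomal protein genes were lower in WT and DA tumours, by -0.31 ± 0.10 and -0.43 ± 0.10 in mean log2 CPM (± SE over 9 libraries). The means per library were 8.99, 8.98 and 8.63 in control, 8.60, 8.59 and 8.49 in WT, and 8.41, 8.43 and 8.45 in DA tumours. Control 3 thus lay close to the WT tumours, and the WT difference comes mainly from controls 1 and 2. Thinning all libraries to the smallest total left -0.31 and -0.43. Thinning keeps each gene's expected share of reads, so at these levels it could hardly move the difference. It therefore does not decide about depth, which goes with the group in tumours. Removing trends with GC content and length left -0.24 ± 0.09 and -0.40 ± 0.09, which argues against these trends as the whole cause. With the share of reads outside annotated exons in the model the WT difference was -0.00384 ± 0.0708, so for WT this share is a candidate explanation, and because it was higher in every WT library than in every control an effect of PTPRR-WT stays open and untested. For DA -0.27 ± 0.05 remained, so the share may account for part of the difference. Whether it accounts for all of it cannot be told, because the slope rests mainly on control tumour 3 against controls 1 and 2. An effect of the construct, RNA quality that the share does not measure, and reads shared with pseudogenes stay open for DA.

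Genes of snoRNA were higher in WT and DA tumours, by 0.73 ± 0.17 and 0.62 ± 0.17 in mean log2 CPM over 122 genes. After thinning 0.67 ± 0.16 and 0.55 ± 0.16 remained. Thinning keeps each gene's expected share of reads here too, so it does not decide about depth. Other traits of the libraries that go with depth were not tested. With the share of reads outside exons in the model 0.79 ± 0.30 and 0.65 ± 0.22 remained. This argues against that share as the whole cause, though here too the slope rests mainly on control tumour 3. Unspliced RNA of host genes, small RNA kept or lost in library preparation, and an effect of the constructs stay open, since none of these was tested.

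In cells WT replicate 1, with 11931867 counts, stood apart: leaving out WT replicate 2 gave 432 calls for WT. On thinned counts the number was 180 to 297 in 5 draws, with a median of 266, so depth may explain part of it, and whether it explains the rest cannot be told apart with 1 library. The rule of 5 draws was set after a first draw had been seen. On thinned counts the library still lay at 37.4 on the first principal component, the others between -9.8 and -4.6. On the full counts it lay at 32.1, so it stood apart at equal depth too. On the second component of the full counts control replicate 2 lay at 27.6. Reads outside annotated exons made up 19.0% in WT replicate 1 and 12.1 to 13.5% in the other cell libraries. Reads placed more than once made up 21.7% in it and 36.8 to 42.7% in the others. Whether these shares account for the calls was not tested, and no biological explanation was tested.

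The splits of the 6 libraries of each tumour comparison number 10, too few for a share under 0.05. For WT, 1 split, the real one, gave as many as 678 genes (highest other 1), and 1 gave as many as 8 lists (highest other 7). The splits that put controls 1 and 2 with WT 1, 2 or 3 gave 7, 7 and 2 lists, and the other false ones 0 to 3. For DA, 1 split gave as many as 495 genes (highest other 0) and 3 as many as 6 lists (highest other 7). The splits that put controls 1 and 2 with DA 1, 2 or 3 gave 6, 5 and 7 lists, and every other false split gave 0. List calls for DA at the preset correlation thus went with controls 1 and 2 being together. For DA against WT, 1 split gave as many as 82 genes (highest other 2) and 3 as many as 4 lists (highest other 5).

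By the test of the difference between tumours and cells, 14 genes differed for WT and 1 for DA. The tumour effect minus the cell effect of WT was 1.61 for PTPRR, 2.37 for GCSH (1.35 in tumours and -1.01 in cells), 2.09 for SNHG12, 1.93 for SNORA31B (1.09 and -0.84) and 1.81 for SNORD59A (1.59 and -0.23). It was -1.75 for TCAF1 (-0.36 and 1.39), -1.70 for BNIP1 (-0.77 and 0.92) and -1.18 for PABPN1 (-0.20 and 0.97). For DA it was 1.80 for PTPRR. In controls PTPRR stood at 257 CPM in cells and 63.5 CPM in tumours, so its larger fold changes in tumours go with lower controls. Of the WT genes only PTPRR was called without cell WT replicate 1.

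Outside the gene counts, ambiguous reads made up 3.32% on average in DA cells and 2.80% in control cells, and every DA library lay above both controls. Reads outside annotated exons made up 38.9% in WT tumours and 30.7% in control tumours, and every WT library lay above all 3 controls.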

How the results depend on the processing

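Chosen after the data were seen were the settings with thinned counts, GC and length offsets, protein-coding genes only, the share of reads outside exons, and the block on compared cell libraries. PTPRR kept its call and direction against control in every setting, from 3.39 to 3.88 for WT and 3.28 to 3.78 for DA in cells, and from 5.17 to 5.26 and 5.27 to 5.34 in tumours. Where not stated otherwise the cause of a change was not tested.

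Leaving out each library in turn gave 1 to 432 genes for WT in cells, 0 to 547 for DA against WT in cells, 183 to 1212 for WT, 124 to 957 for DA and 0 to 386 for DA against WT in tumours, and 1 to 926 for the WT and 1 to 19 for the DA difference between tumours and cells. Lists ran from 0 to 1 for WT, 0 to 2 for DA and 0 to 2 for DA against WT in cells, and from 5 to 9, 4 to 8 and 3 to 6 in tumours. A library left out ended 330 calls of named genes and 17 list calls and left 660 and 157. A lone cell library is assumed to vary like the others.

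Fits with the share of reads outside exons in the model called 5, 65 and 48 genes for WT, DA and DA against WT in tumours, of which 5, 61 and 20 were among those called without it, and 83 calls of named genes ended and 11 held. With the share in the model CCNG1 for WT changed sign to 0.00378, near 0, and the cholesterol list for WT to 0.0623. For WT in tumours 3 lists were called, 2 of them among the 8 called without it, and 0 for DA in cells. Standard errors of named genes grew for 43 of 43 in WT and 34 of 38 in DA. RNU4ATAC for WT went from 3.61 ± 0.34 to 4.09 ± 0.70 and NDRG1 from -0.88 ± 0.10 to -0.59 ± 0.15, and RPL23A for DA from -0.97 ± 0.10 to -0.81 ± 0.09. Of the calls lost, 7 of 42 for WT, 5 of 30 for DA and 4 of 12 for DA against WT had a fold change as large or larger.

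With the replicate block tumours gave 1123, 1072 and 403 genes, the DA difference 4, and WT and DA shared 422 calls. Crossing the replicate block of the 4 WT and control cell libraries gave 3 genes, and 1 as numbered. With no count filter WT gave 3 and DA against WT 11 genes in cells, DA against WT 381 in tumours, and the differences 241 for WT and 13 for DA, where genes near 0 were added. DESeq2 gave 206 genes for DA against WT in tumours and 64 and 22 for the differences. Thinned counts gave 47 for DA against WT in tumours and 7 and 2 for the differences, from fewer counts. The compared groups alone gave 146 for DA against WT in tumours. The WT difference gave 23 with the CPM filter and 2 with protein-coding genes only, and the DA difference 3 without robust estimation.

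An estimated correlation left 0 lists for DA and DA against WT in cells and 0 for WT, DA and DA against WT in tumours. With fry 0 and 0 lists were called for DA and DA against WT in cells, and 1 for WT and 1 for DA against WT in tumours. Lists for DA against WT in cells numbered 2 on thinned counts and 2 with GC and length offsets.

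All other settings stayed within 1.5 times the count reported. For WT in tumours upper-quartile scaling gave 299 higher and 364 lower genes and the offsets 293 and 296, and for DA the offsets gave 228 and 325. Of the calls of named genes, 7 were lost and 97 kept in DESeq2, 23 and 81 on thinned counts, 18 and 77 with the offsets and 12 and 83 with the compared groups alone. In DESeq2 a gene left without an adjusted p counts as lost. In simulated cell counts with the real library sizes, 1393952 to 2085431 in all but 1, 44.8 to 47.8% of 2-fold and 93.9 to 100% of 4-fold changes were called, which holds for depth, spread and 2 libraries per group together.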

Other observations

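The gene groups and their tests here were chosen after the data were seen, as were fry and camera on the tumour genes in cells.

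Mitochondrial ribosomal protein genes were lower in DA than in control tumours as a group (75 tested, 3 lower and 1 higher, camera adjusted p = 0.033, adjusted p = 0.855 with an estimated correlation), with MRPL14 and MRPL58 among the genes called. Genes of snRNP and LSM proteins, which form the core of spliceosomal particles, were lower in DA than in WT tumours (24 tested, camera adjusted p = 0.0241, adjusted p = 0.665 with an estimated correlation), with SNRPE and LSM3 called. Proteasome, histone and ZNF genes had no call as groups in any of the 3 tumour comparisons.

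By gene type, the genes that rose in WT tumours held 26 processed pseudogenes (Fisher's exact test across genes, p = 1.80e-06), 8 genes of the type misc_RNA (Fisher's exact test, p = 0.00019) and 5 small nuclear RNA genes (Fisher's exact test, p = 0.00411). Protein-coding genes made up 80.4% of genes tested, 96.1% of those that fell and 52.1% of those that rose for WT, and 92.4% and 65.4% for DA.

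Genes called in WT tumours were tested as groups in cells. With fry, p was 0.63 for genes that rose and 0.529 for those that fell, and for DA 0.738 and 0.722. With camera, p was 0.0157 for genes that rose in WT tumours, in the opposite direction, and 0.0114 for those that fell, in the same direction, and 0.682 and 0.523 for DA.

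The first principal component held 30.1% of the variance in tumours, with controls 1 and 2 at -38.8 and -35.3, control 3 at -9.79, WT between 12.7 and 27.9 and DA between 2.64 and 8.11.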
